A study of Homo sapiens with 6 samples.

How the data were processed

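PC3 cells carrying a lentiviral hairpin against CTSZ or a control vector were selected with an antibiotic as stable populations, per the labels' protocols, and total RNA taken with TRIzol went into a SMARTer mRNA-seq library preparation. The submitters' processing notes list fastp, RSEM and the build GRCh38.p13, without versions or order. The aligner, the annotation release and any use of strand are not given in the sources used here. The authors deposited 1 table of TPM values for the 6 libraries, in which every column has the same sum. TPM divides by transcript length and by the library total, so a rise of some genes lowers others. Values are comparable only as shares of measured RNA, and read totals are lost. The depth is unknown, so no counting interval or detection floor was computed. Columns were assigned to samples by their names, which match the sample descriptions apart from a separator, and groups (3 shControl and 3 shCTSZ) were taken from the same descriptions. All columns of per-sample values were used.

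The table holds 61895 rows. Of these, 61541 carry an Ensembl gene ID, 61369 of which were paired with a name, and 354 carry an MSTRG name and no gene ID; the latter hold 0.328% of TPM. Gene types, positions, transcript lengths and GC content came from GENCODE 29 on GRCh38, as the median over a gene's transcripts, and covered 96.3% of the 14874 rows kept at a mean of at least 1 TPM over the 6 libraries. Counting by RSEM divides reads between near-identical copies by estimate, and overlapping genes share reads where strand is not used. Many named genes overlap another kept gene, and only some are pointed out in the text.

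The main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with group as the only term, empirical Bayes moderation with a mean-variance trend, and Benjamini-Hochberg adjustment over the kept genes at 0.05. A count test was not used, since TPM are not counts. An exact permutation test of 3 against 3 libraries cannot give a two-sided p below 0.1, so single genes were not tested that way. Before the data were examined, 34 gene lists were fixed from general knowledge of prostate cancer, lysosomal proteases, cytokines and hairpin delivery, including markers of other cell types; 33 had at least 3 kept members. They were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 33 lists. No list was called with an estimated correlation, and 5 then had an unadjusted p under 0.05. Members are also counted with p-values adjusted over the list alone. Some genes are members of several lists, so results of such lists are not independent of one another.

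Genes were named by a rule fixed in the same way: the 4 genes of the title; the 10 largest rises and 10 largest falls among genes past the threshold with non-overlapping groups, a mean of at least 5 TPM in the higher group and a symbol that is not a placeholder; and up to 4 members past the threshold with the smallest adjusted p in each tested list, or 2 given as values only where none passed. A selection of these is given in the text, and CCL3 was named outside this rule after its value was seen.

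The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalisation, rescaling without mitochondrially encoded genes, moderation without the trend, weights per library, the replicate number as a block, leaving out each library in turn, a test against a 1.5-fold change, camera with an estimated correlation or on ranks, and fry. A further 2 were added after seeing the data: removal of each library's trend over GC content and log2 transcript length by natural splines with 5 degrees of freedom each, over the 14324 genes with GC content and length, and a fit of protein-coding genes only, rescaled to equal totals.

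The fit was tested on simulated data drawn on the log scale from the mean and residual spread of each kept gene, in 5 runs with 200 changed genes each; 14873 genes were fitted. At 1.5-, 2- and 4-fold it recovered 51.9%, 75.5% and 94.2% of the changed genes, 4.8% of calls were false, and a list shifted by 0.3 was called in 5 of 5 runs with 1 other list called over all runs. Genes were drawn independently of one another, while the estimated correlation within the real lists reached 0.49, for cytosolic ribosomal proteins. Far fewer genes were changed than passed the threshold in the data, so these rates may not hold there. A simulated GC trend with no gene changed, of -0.015 log2 per percent, gave 595 calls, and 0 after the trend was removed. That trend was a straight line, the same in every shCTSZ library, which the splines follow by construction. The result therefore checks only that the removal runs, not how well it works on the real trend. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.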

Results

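RNA was sequenced from PC3 cells, an established human prostate cancer line that grows without androgen, after stable lentiviral delivery of short hairpin RNA. In 3 libraries the target was CTSZ, which encodes cathepsin Z, a lysosomal cysteine protease (shCTSZ), and 3 libraries came from control vector cells (shControl). The design text asks how CTSZ regulates cytokine secretion, and the title places it in macrophage recruitment through TRA2A, IL-32 and ITGA5. Expression was given as TPM, a share of each library that keeps no read totals, so the depth is unknown and no counting interval is given. The shControl libraries listed 24714, 24407 and 24299 genes above 0, and the shCTSZ libraries 23679, 24004 and 24045. Mitochondrially encoded genes held 5.32%, 5.38% and 5.10% of TPM in shControl and 6.38%, 6.24% and 6.30% in shCTSZ. The labels do not say whether the libraries of a group came from separate cultures, or whether 1 hairpin or several were used against CTSZ, so p-values measure only the spread between these samples. Values are mean TPM ± SD with n = 3 per group. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and "rose" and "fell" are used of genes with a limma adjusted p under 0.05.

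CTSZ (ENSG00000101160, GRCh38 chromosome 20, 58995185 to 59007247, minus strand) fell from 92.8 ± 2.1 TPM in shControl to 19.9 ± 1.7 TPM in shCTSZ. The control libraries held 90.6, 94.7 and 93.2 TPM and the knockdown libraries 21.7, 18.3 and 19.7 TPM, which is 21.4% of the control mean. The log2 fold change was -2.17 (SE 0.066, limma adjusted p = 2.49e-05). Of the other genes in the title, IL32, a pro-inflammatory cytokine gene (ENSG00000008517, chromosome 16, 3065297 to 3082192), fell from 5.72 ± 0.38 to 1.73 ± 0.71 TPM (log2 fold change -1.33, adjusted p = 0.00308). ITGA5, the alpha subunit of the fibronectin receptor (ENSG00000161638, chromosome 12, 54395261 to 54419460), fell from 73.6 ± 5.7 to 52.4 ± 5.3 TPM (log2 fold change -0.48, adjusted p = 0.00634). TRA2A, a splicing regulator (ENSG00000164548, chromosome 7, 23504780 to 23532041), held 120 ± 10 TPM in shControl and 111 ± 8.5 TPM in shCTSZ, and its groups overlapped (log2 fold change -0.10, 95% interval -0.29 to 0.08, adjusted p = 0.349). TRA2A passed the threshold only when the trend of each library over GC content and transcript length was removed, an alternative chosen after seeing the data (log2 fold change -0.24, adjusted p = 0.0244; adjusted p over all alternatives 0.0244 to 0.696). Of 8 genes in a list of this axis and its partners, 2 rose and 3 fell (4 and 3 adjusted over the list alone), with ITGB3 rising from 3.25 ± 0.14 to 5.06 ± 0.20 TPM. The list as a whole was not called (camera adjusted p = 0.518).

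**Figure D1:**
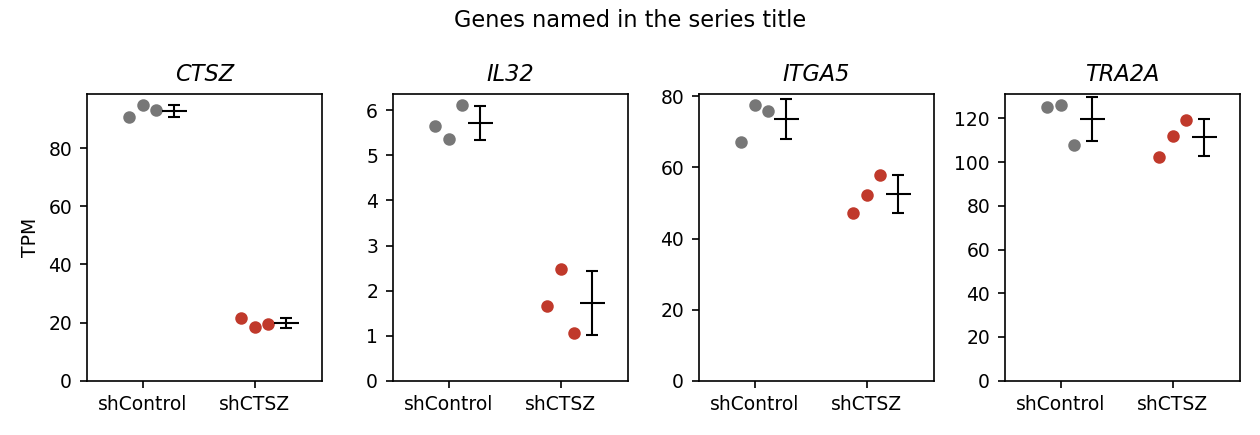
TPM (vertical axes, from 0) of CTSZ, IL32, ITGA5 and TRA2A in the 3 shControl (grey) and 3 shCTSZ (red) libraries, with the group mean and SD beside the points. CTSZ, IL32 and ITGA5 do not overlap between the groups, and TRA2A does.

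Of 14874 genes with a mean of at least 1 TPM, 5135 (34.5%) passed the threshold, 2950 higher and 2185 lower in shCTSZ. This balance depended on scaling, with 2463 higher and 2661 lower under median-of-ratios size factors. The median absolute log2 fold change of these genes was 0.40. At least 2-fold, 67 genes were higher and 311 lower, and of these 35 and 108 were protein-coding. Groups did not overlap for 7487 genes (50.3%, against 10% by chance). The count at least 2-fold depended on settings, from 118 genes at a pseudocount of 5 to 568 at 0.1. The fit with the GC and length trend removed held 259 of the 378 genes at least 2-fold and gave 249. The first principal component held 40.6% of the variance and separated the groups.

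Among the largest rises were THBS1, the matrix glycoprotein thrombospondin 1, from 72.4 ± 7.5 to 208 ± 4.9 TPM (log2 fold change 1.51, adjusted p = 8.32e-05), and CAVIN2, a caveolar coat protein gene, from 6.07 ± 0.59 to 16.2 ± 0.76 TPM. PRKCE, a protein kinase C isoform, rose from 6.52 ± 1.8 to 16.4 ± 0.72 TPM and NIPAL1 from 1.71 ± 0.62 to 5.57 ± 0.93 TPM. NIPAL1 overlaps NFXL1 on the other strand, which rose too (log2 fold change 0.63), and THBS1 overlaps FSIP1 and THBS1-AS1, so reads may be shared. Other genes among the 10 largest rises are also uncertain. SNORA73A was listed at 0 in every shControl library and at 6.11 ± 1.6 TPM in shCTSZ, and lies inside RCC1 and SNHG3. RNU6-447P is a small RNA pseudogene, BLOC1S5-TXNDC5 is a readthrough of BLOC1S5 and TXNDC5, and PPP1R12A-AS2 overlaps PPP1R12A on the other strand, with no statement of stranded counting. The call of BLOC1S5-TXNDC5 was lost with no filter on low values (adjusted p = 0.0629, over its alternatives 0.00549 to 0.0629). The call of PPP1R12A-AS2 was lost without shCTSZ replicate 2 (adjusted p = 0.0501) and with no filter (0.058), out of a range from 0.00582 to 0.058. LCOR, a nuclear receptor corepressor gene, held 7.17 ± 2.6 TPM in shControl and 23.6 ± 11 TPM in shCTSZ, and lost its call without shControl replicate 1 or 2 or shCTSZ replicate 1 or 2 (adjusted p 0.0547 to 0.0775). It also lost it with no filter (0.084), with a replicate block (0.0509) and with the GC and length trend removed (0.0569), so the call of LCOR was lost under 7 of 18 alternatives. CREBBP, a histone acetyltransferase gene, held 22.5 ± 1.1 and 62.2 ± 32 TPM and lost its call on leaving out any library but shCTSZ replicate 2 (adjusted p 0.0785 to 0.103). The call of CREBBP was also lost with no filter (adjusted p = 0.115) and without the trend in the variance model (0.0678).

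Among the largest falls were DHRS2, a short-chain dehydrogenase gene, from 551 ± 58 to 100.3 ± 9.5 TPM (log2 fold change -2.45, adjusted p = 2.7e-05), and TCN2, the vitamin B12 carrier transcobalamin 2, from 25.1 ± 2.5 to 2.23 ± 0.31 TPM (log2 fold change -3.02). RGMA, a repulsive guidance molecule and BMP co-receptor, fell from 45.1 ± 6.5 to 7.30 ± 3.2 TPM, and ART3 from 21.8 ± 4.4 to 3.18 ± 0.43 TPM. TCN2 overlaps PES1 and ART3 overlaps CXCL11, both on the other strand. The noncoding RNAs TM4SF18-AS1 (33.4 ± 3.7 to 5.68 ± 0.11 TPM) and CDKN2A-DT (16.9 ± 2.0 to 2.54 ± 0.44 TPM) also fell. TM4SF18-AS1 overlaps TM4SF18 on the other strand, while TM4SF18 itself held 30.4 ± 3.8 and 30.5 ± 5.3 TPM. FRG2B (14.2 ± 2.8 to 0.86 ± 0.31 TPM), RPL23AP49 and RNU6-1069P belong to families with similar copies, so their values are uncertain.

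**Figure D2:**
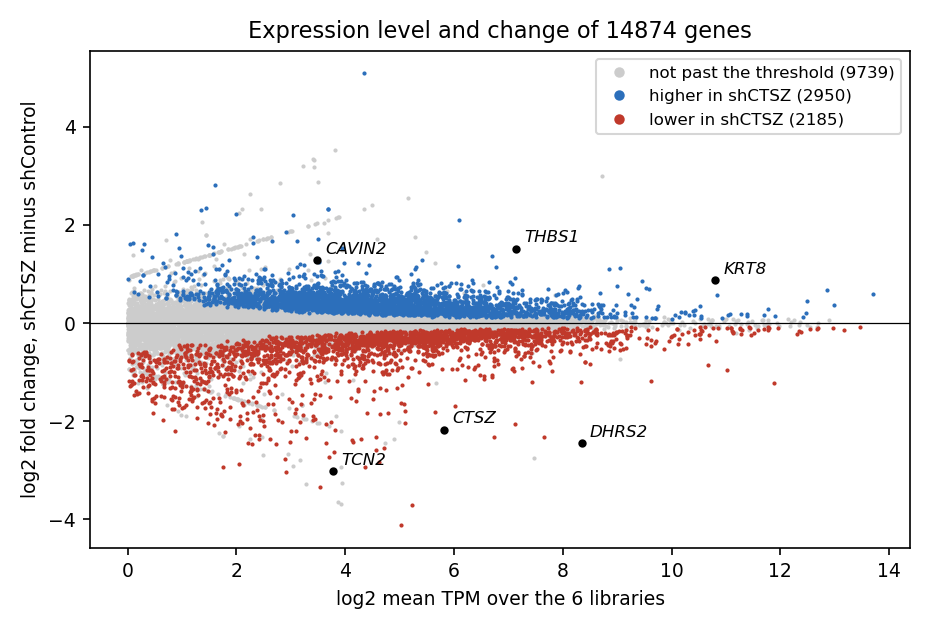
Each point is 1 of 14874 genes, with the log2 mean TPM over the 6 libraries on the horizontal axis and the log2 fold change (shCTSZ minus shControl) on the vertical axis. The 2950 genes higher in shCTSZ are blue, the 2185 lower are red and the rest are grey.

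The cytokine question of the design was addressed, for transcripts only, with lists fixed before the data were examined. Secretion of the proteins was not measured. Of 25 measured interleukins and other cytokines 14 fell and 1 rose (16 and 1 adjusted over the list alone). The camera adjusted p was 1.65e-05, and adjusted p = 0.136 with an estimated correlation. GDF15, a stress-induced TGF-beta family cytokine, fell from 5274 ± 212 to 2269 ± 177 TPM. LTB (lymphotoxin beta) fell from 8.55 ± 0.48 to 3.17 ± 0.89 TPM and TGFB1 from 122 ± 0.81 to 86.4 ± 4.6 TPM. INHBA, the activin A subunit, was the member that rose, from 56.9 ± 5.0 to 104 ± 2.5 TPM. Of 17 tumour-derived macrophage attractants and polarisers 9 fell and none rose (11 and none adjusted over the list alone; adjusted p = 1.65e-05, and adjusted p = 0.162 with an estimated correlation). Among them were CCL5 (280 ± 6.7 to 172 ± 4.2 TPM), ANXA1 (553 ± 13 to 374 ± 11 TPM) and IL6 (143 ± 2.2 to 120 ± 5.8 TPM). The attractant list shares members with the cytokine list, TGFB1 and IL6 included, and with the chemokine list, CCL5 included. The 12 measured chemokines moved both ways, 3 up and 5 down under both adjustments, and the list was not called (adjusted p = 0.169), though it was with no filter on low values (0.0237). CCL3, an attractant of macrophages that is only in the chemokine list, rose from 29.3 ± 3.1 to 48.4 ± 2.4 TPM, though it has near-identical copies. CXCL8, which attracts neutrophils, rose from 236 ± 15 to 386 ± 12 TPM, while CCL20 fell from 61.6 ± 2.7 to 38.8 ± 0.93 TPM and CXCL2 from 191 ± 3.1 to 121 ± 12 TPM. Growth factors also divided, with 4 of 15 up and 4 down under both adjustments (adjusted p = 0.298). The EGF receptor ligand AREG fell from 297 ± 9.6 to 150 ± 4.0 TPM, whereas HBEGF, another ligand of that receptor, rose from 47.8 ± 4.0 to 84.2 ± 1.8 TPM.

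**Figure D3:**
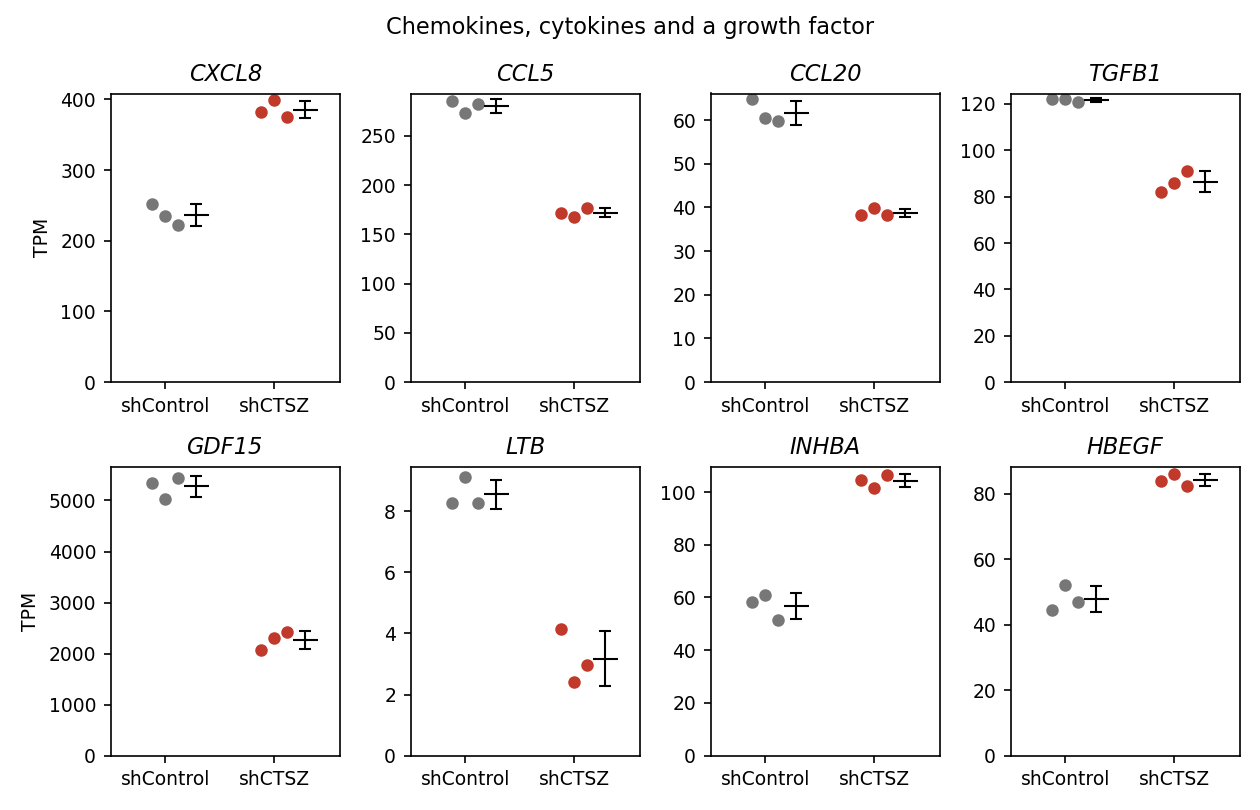
TPM (vertical axes, from 0) of 8 genes for secreted or membrane-bound signalling proteins in the 3 shControl (grey) and 3 shCTSZ (red) libraries, with the group mean and SD beside the points. CXCL8, INHBA and HBEGF are higher and CCL5, CCL20, TGFB1, GDF15 and LTB lower in every shCTSZ library.

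Interferon-stimulated genes were lower in the knockdown cells. Of 36 measured members 21 fell and none rose (22 and 1 adjusted over the list alone), with a median log2 fold change of -0.54 (camera adjusted p = 2.55e-09; adjusted p = 0.162 with an estimated correlation). ISG15, a ubiquitin-like modifier, fell from 1095 ± 81 to 483 ± 14 TPM, and OASL from 129 ± 3.5 to 58.4 ± 1.9 TPM. IFIT1, which binds viral RNA, fell from 48.7 ± 1.0 to 22.2 ± 0.65 TPM and the transcription factor IRF7 from 82.4 ± 2.6 to 42.5 ± 1.7 TPM. NF-kB targets fell in 14 of 31 cases and rose in 3 (16 and 4 adjusted over the list alone; adjusted p = 1.79e-04, and adjusted p = 0.573 with an estimated correlation). BCL3 fell from 24.6 ± 1.8 to 12.1 ± 1.0 TPM and NFKB2 from 295 ± 4.3 to 199 ± 14 TPM. CXCL8 and CCL20, given above as chemokines, are also in the NF-kB list. They have its smallest limma adjusted p (2.66e-04 and 2.9e-04), and CXCL8 rose while CCL20 fell. Of 17 genes of antigen processing and MHC class I 6 fell and 4 rose under both adjustments, and the list was not called (adjusted p = 0.169). HLA-B fell from 193 ± 12 to 125 ± 6.1 TPM and HLA-E from 200.3 ± 2.5 to 144 ± 8.7 TPM. These genes share sequence with one another, so the division of reads between them is uncertain.

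Of 37 genes of DNA replication and S phase 26 rose and none fell (27 adjusted over the list alone), with a median log2 fold change of 0.39 (camera adjusted p = 1.4e-08; adjusted p = 0.421 with an estimated correlation). The replicative helicase subunit MCM4 rose from 71.0 ± 3.1 to 129 ± 12 TPM, MCM2 from 44.8 ± 0.62 to 76.1 ± 4.7 TPM and UHRF1, a factor for maintenance of DNA methylation, from 63.2 ± 3.1 to 100.2 ± 1.9 TPM. Of 34 replication-dependent histones 14 fell and none rose under both adjustments (adjusted p = 1.21e-05; adjusted p = 0.136 with an estimated correlation). H2BC12 went from 246 ± 13 to 133 ± 5.5 TPM and H1-2 from 278 ± 14 to 157 ± 7.4 TPM. Histone copies are similar in sequence and their division is uncertain. Of 30 genes of mitosis and G2/M 13 rose and 4 fell (15 and 5 adjusted over the list alone; adjusted p = 0.15, not called). The mitosis list was called with no filter (adjusted p = 0.00774), and with the GC and length trend removed it had 6 rises and 7 falls (0.948). KIF20A rose from 35.7 ± 1.8 to 59.4 ± 4.4 TPM and CENPF fell from 36.6 ± 4.3 to 21.1 ± 1.9 TPM. Of 21 p53 targets 7 fell and 3 rose under both adjustments (adjusted p = 0.256, not called). The cell cycle inhibitor CDKN1A fell from 394 ± 8.5 to 324 ± 6.1 TPM and PLK2 rose from 97.7 ± 9.9 to 169 ± 16 TPM.

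Of 23 cholesterol synthesis genes 16 rose and 1 fell (18 and 2 adjusted over the list alone), with a median log2 fold change of 0.41 (camera adjusted p = 5.74e-06; adjusted p = 0.162 with an estimated correlation). DHCR7, an enzyme of its last steps, rose from 140 ± 1.5 to 198 ± 1.8 TPM, and ACAT2 rose from 117 ± 5.6 to 188 ± 4.2 TPM. Nuclear genes of oxidative phosphorylation rose in 22 of 47 cases and fell in 3 (22 and 4 adjusted over the list alone; adjusted p = 4.39e-04, and adjusted p = 0.573 with an estimated correlation). SDHC rose from 72.1 ± 1.9 to 103 ± 3.2 TPM. Mitochondrially encoded messengers rose in 10 of 13 cases and fell in 1 under both adjustments (adjusted p = 1.79e-04, and adjusted p = 0.525 with an estimated correlation). MT-CO1 rose from 7119 ± 261 to 9160 ± 174 TPM. The mitochondrially encoded list was no longer called with the GC and length trend removed (adjusted p = 0.0779, over its alternatives 7.98e-06 to 0.525). Cytosolic ribosomal proteins fell in 34 of 72 cases and rose in 1 (36 and 2 adjusted over the list alone), by small amounts (camera adjusted p = 3.67e-08; adjusted p = 0.671 with an estimated correlation). Their median log2 fold change was -0.09, and RPS6 fell from 1640 ± 33 to 1305 ± 33 TPM. Of 32 targets of the integrated stress response 16 fell and 5 rose (16 and 6 adjusted over the list alone; adjusted p = 0.00171, and adjusted p = 0.626 with an estimated correlation). Among them were DDIT4 (433 ± 26 to 250 ± 11 TPM) and ATF3 (139 ± 13 to 81.9 ± 5.3 TPM). Endoplasmic reticulum chaperones and related genes were not called as a list (9 of 23 rose and 4 fell, 10 and 4 adjusted over the list alone; adjusted p = 0.379). HSPA5, the main chaperone of that compartment, fell from 388 ± 23 to 276 ± 10 TPM. Hypoxia and glycolysis genes were not called either (4 of 33 rose and 7 fell, 5 and 7 adjusted over the list alone; adjusted p = 0.169), though they were without shControl replicate 1 (0.0181). The lactate exporter SLC16A3 fell from 218 ± 4.4 to 151 ± 7.2 TPM and the glycolytic enzyme PGAM1 rose from 260 ± 6.8 to 377 ± 27 TPM.

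YAP/TAZ targets rose in 13 of 24 cases and fell in 2 under both adjustments (camera adjusted p = 0.00495; adjusted p = 0.671 with an estimated correlation). CCN2, a matricellular growth factor gene, rose from 336 ± 28 to 726 ± 19 TPM and ANKRD1 from 502 ± 36 to 910.1 ± 19 TPM. Collagens, laminins and other matrix genes fell in 10 of 23 cases and rose in 4 (12 and 4 adjusted over the list alone; adjusted p = 0.00348, and adjusted p = 0.573 with an estimated correlation). LAMA5 fell from 221 ± 8.4 to 127 ± 12 TPM and AGRN from 135 ± 3.7 to 78.6 ± 2.2 TPM. Immediate early genes fell in 13 of 29 cases and rose in 6 under both adjustments (adjusted p = 0.0225, and adjusted p = 0.671 with an estimated correlation), among them KLF4 (32.3 ± 1.4 to 17.6 ± 0.73 TPM). The call of that list was lost without shCTSZ replicate 1 (adjusted p = 0.0642) and on ranks (0.0739), out of a range over its alternatives from 0.00574 to 0.671. Integrins as a list were not called (5 of 14 rose and 3 fell, 6 and 4 adjusted over the list alone; adjusted p = 0.476). ITGA2 rose from 3.09 ± 0.41 to 7.16 ± 0.48 TPM and ITGA3 fell from 453 ± 16 to 343 ± 27 TPM. Matrix proteases and the plasminogen system (4 of 17 rose and 6 fell, 4 and 7 adjusted over the list alone; adjusted p = 0.462), epithelial genes (4 of 20 rose and 4 fell under both adjustments; adjusted p = 0.586) and mesenchymal genes (8 of 25 rose and 4 fell under both adjustments; adjusted p = 0.476) also went both ways. The protease gene ADAM9 rose from 37.5 ± 1.1 to 65.4 ± 2.4 TPM. The epithelial keratin KRT8 rose from 1256 ± 5.4 to 2304 ± 98 TPM while ELF3, an epithelial transcription factor, fell from 4.41 ± 0.98 to 0.75 ± 0.27 TPM. KRT8 overlaps KRT18 on the other strand, so the division of their reads is uncertain.

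**Figure D4:**
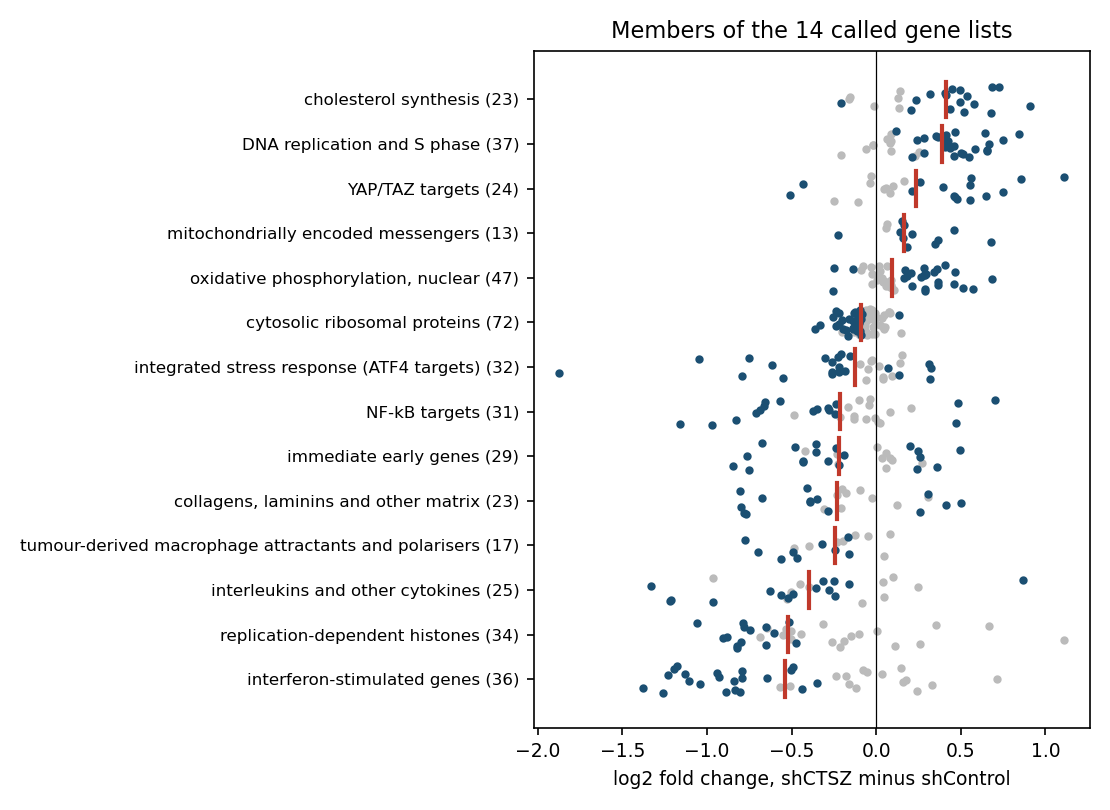
Log2 fold change (horizontal axis, shCTSZ minus shControl) of every measured member of the 14 lists called by camera with a preset correlation, with the number of members in brackets. Dark points passed the threshold, grey points did not, and red bars mark medians, which run from -0.54 for interferon-stimulated genes to 0.41 for cholesterol synthesis.

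Other cathepsins changed little beside CTSZ. Of 12 measured cathepsins and inhibitors 3 rose and 1, CTSZ itself, fell under both adjustments (camera adjusted p = 0.86, not called), and the mean log2 fold change (-0.15) and the median (0.04) differed in sign. The inhibitor CSTB rose from 182 ± 4.1 to 212 ± 7.5 TPM. CTSL (58.9 ± 3.7 to 68.7 ± 1.7 TPM) and CTSC (80.6 ± 0.52 to 88.0 ± 2.1 TPM) rose by less than 1.2-fold and lost their calls under 5 and 11 of 18 alternatives. Lysosomal genes were not called (11 of 38 rose and 8 fell, 17 and 9 adjusted over the list alone; adjusted p = 0.352). SQSTM1, an autophagy receptor, fell from 521 ± 21 to 384 ± 9.7 TPM and the proton pump subunit ATP6V0D1 rose from 35.1 ± 0.39 to 54.4 ± 3.9 TPM. Of 40 splicing factors of the SR, TRA2 and hnRNP families 15 rose and 5 fell (18 and 7 adjusted over the list alone; adjusted p = 0.055, not called). SRSF1 rose from 93.7 ± 9.4 to 167 ± 6.2 TPM and SRSF6 from 85.5 ± 0.20 to 128 ± 2.6 TPM. The splicing list was called higher with no filter (adjusted p = 0.00108), under quantile normalisation (0.0342) and without mitochondrially encoded genes (0.0404). It was also called without shControl replicate 2 (0.03) or shCTSZ replicate 3 (0.0452). With the GC and length trend removed that list had 11 rises, 12 falls and an adjusted p of 0.942 in the other direction, over its alternatives 0.00108 to 0.942. Of 6 measured neighbours of CTSZ on chromosome 20, 1 rose and 2 fell under both adjustments (adjusted p = 0.509), NPEPL1 from 25.5 ± 1.5 to 19.4 ± 0.95 TPM. NPEPL1 overlaps the readthrough STX16-NPEPL1 on the same strand, so the division of their reads is uncertain. That readthrough is not in the list and rose (log2 fold change 0.22, limma adjusted p = 0.0354). The call of PRELID3B, which rose, was lost with the GC and length trend removed (adjusted p = 0.23), and that of GNAS, which fell, without the trend in the variance model (0.0691).

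Of 20 androgen receptor and luminal prostate genes 8 were measured at a mean of 1 TPM or more, and 1 fell under both adjustments (adjusted p = 0.796): NDRG1, from 48.6 ± 4.8 to 28.9 ± 7.6 TPM, a call lost without shControl replicate 3 (adjusted p = 0.0524) and with no filter (0.0516), out of a range for NDRG1 from 0.00379 to 0.0524. Of 4 measured neuroendocrine genes 3 fell under both adjustments (adjusted p = 0.055, not called). The neuroendocrine list was called without shControl replicate 1 (adjusted p = 0.0277) or 2 (0.0418) and over protein-coding genes only (0.0468). FOXA2 fell from 6.48 ± 0.54 to 4.29 ± 0.08 TPM. The calls of ENO2 and SYP were lost under 7 and 10 of 18 alternatives, at adjusted p up to 0.0785 and 0.119. Markers of other cell types were nearly absent. Only 2 of 20 macrophage and other leukocyte markers reached a mean of 1 TPM, too few to test, with none past the threshold under either adjustment. Of 16 fibroblast and endothelial markers 3 did, with none past the threshold under either adjustment (adjusted p = 0.447), ACTA2 at 2.42 ± 0.45 and 1.27 ± 0.51 TPM and EGFL7 at 22.4 ± 0.92 and 20.2 ± 0.80 TPM. EGFL7 passed it under median-of-ratios scaling (adjusted p = 0.0308) and quantile normalisation (0.0272). ACTA2 passed it with weights per library (adjusted p = 0.0482) and over protein-coding genes only (0.0306).

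Fold changes followed GC content. Across 11896 protein-coding genes, which are not independent replicates, Spearman's rho between transcript GC content and log2 fold change was -0.35. In the decile with GC from 42.87% to 45.17% the median log2 fold change was 0.17, with 35.6% of genes higher and 5.04% lower. In the decile from 62.63% to 77.32% it was -0.14, with 6.14% higher and 31.8% lower. The deviation of each library from the mean of the 6 had a rho with GC content of 0.18, 0.27 and 0.40 in shControl and of -0.24, -0.38 and -0.25 in shCTSZ, so the groups did not overlap. The median GC content was 50.6% over protein-coding genes, 49.8% over the interferon-stimulated genes, 54.9% over the cytokines and 53.3% over the macrophage attractants. It was 55.6% over the histones, 50.8% over the S phase genes and 50.2% over cholesterol synthesis. It was 56.4% over both NF-kB targets and immediate early genes, 58.6% over matrix genes, 55.4% over stress response targets, 51.5% over ribosomal proteins, 52.4% over YAP/TAZ targets and 43.8% over splicing factors. With the trend over GC content and length removed, rho was -0.03 over protein-coding genes. Over 2428 genes that are not protein-coding it went from -0.04 to 0.11, so the removal left them with a trend of the opposite sign. In that fit, 4602 of 14324 genes passed the threshold. Of the 4948 of these genes called before, 3625 were called in the same direction, and 13 of the 14 called lists were called the same way at the preset correlation. With an estimated correlation no list was called after the removal (lowest camera adjusted p = 0.137).

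**Figure D5:**
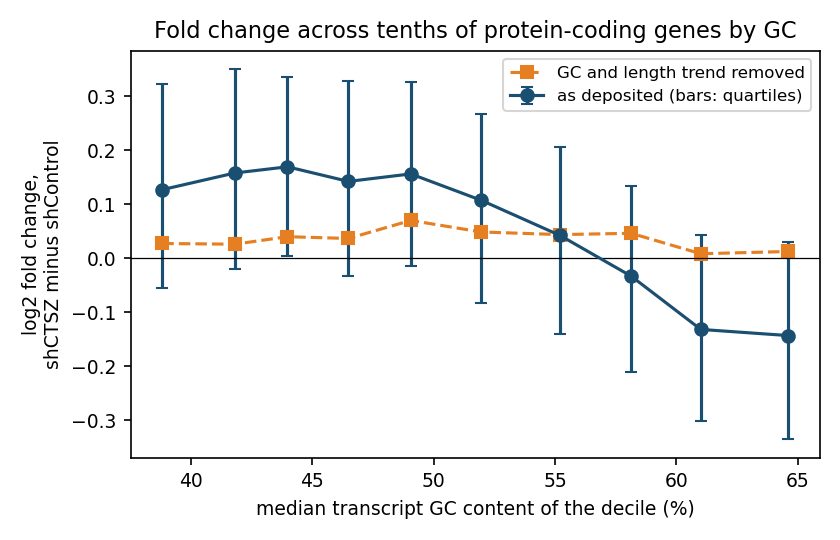
Median log2 fold change (vertical axis, shCTSZ minus shControl) of the GC deciles of 11896 protein-coding genes against their median transcript GC content in percent (horizontal axis). Circles with bars give the median and quartiles of the values as deposited, from 0.17 in the third decile to -0.14 in the last, and squares the medians after the trend over GC content and length was removed.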

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

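The GC and length correction and the fit of protein-coding genes alone were chosen after seeing the data; the other settings were fixed before. The count of genes past the threshold with no minimum size of change stayed between 3869 and 5335 under these settings, and CTSZ fell in each. No gene past the threshold in the main test passed it in the opposite direction under any setting. Of 133 named genes past the threshold, 122 stayed past it in the same direction under every alternative that tested them; filters, gene type or a missing GC value left some genes out of 1 or 2 of the 18. Single alternatives moved the count at least 2-fold: from 378 genes (67 higher, 311 lower) to 568 at a pseudocount of 0.1 (121 higher), 118 at 5 (21 and 97), 176 at a mean of at least 5 TPM (38 and 138), 249 (199 lower) in the fit with the GC and length trend removed, 161 over protein-coding genes only (39 and 122), and, with the 2-fold minimum replaced by a limma test against a 1.5-fold change, 171 (23 and 148). A larger pseudocount and a higher minimum shrink or remove changes of low genes by construction. The protein-coding fit both drops other types and rescales: 35 higher and 108 lower protein-coding genes were at least 2-fold before it, and the cause of the rest of its move was not tested. The GC fit leaves out 550 genes without GC content, which hold 119 of the 378; among the genes it keeps, the count went from 259 to 249. Median-of-ratios scaling gave 2463 higher and 2661 lower.

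The 14 called lists became 0 with an estimated correlation, where 5 had an unadjusted p under 0.05, and 27 (one direction) or 33 (either direction) with fry, which does not compare a list with other genes. Lists that were not called changed sign in some settings: cathepsins with no filter (adjusted p = 0.936), on ranks (0.951), with the GC trend removed (0.517) and on leaving out shControl replicate 3 or shCTSZ replicate 3 (0.932 and 0.908; over all leave-one-out fits 0.658 to 0.932); chaperones (0.942) and splicing factors (0.942) with the GC trend removed; epithelial genes at a mean of at least 5 TPM (0.473); and with fry the androgen receptor list (0.681) and matrix proteases (0.849). EGFL7, not past the threshold, went to a log2 fold change of 0.0272 with the GC trend removed, and passed it under median-of-ratios scaling (-0.19) and quantile normalisation (-0.20). The cause of these changes was not tested.

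Replicate numbers were taken from the sample descriptions, and the labels do not say that they pair the samples. Deviations of same-numbered libraries had correlations of -0.09, -0.02 and -0.04. These values show no shared deviation but cannot exclude a pairing without one. With a replicate block 4026 genes passed the threshold (2236 higher, 1790 lower), and the 2-fold count was 375. Since TPM keep no depth, counting error of low genes is not known.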

Other observations

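The gene families and the tests in this part were chosen after the results were seen, apart from the 2 tests of the GC trend over other sets of genes, and the bounds for the splits were also set afterwards. The interferon lambda genes, which encode the epithelial type III interferons, fell in the knockdown cells: IFNL1 from 78.8 ± 5.1 to 21.6 ± 1.1 TPM (log2 fold change -1.82, limma adjusted p = 2.7e-05, lower in 3 of 3 libraries), IFNL2 from 51.8 ± 5.9 to 15.8 ± 1.2 TPM and IFNL3 from 53.8 ± 0.39 to 14.9 ± 1.6 TPM. IFNL2 and IFNL3 are close copies whose division of reads is uncertain. IFNB1 held 2.55 ± 0.60 and 1.47 ± 0.30 TPM and did not pass the threshold (adjusted p = 0.0688), but did with the GC and length trend removed (0.0341). Of 5 interferon receptor genes 1 rose and none fell, and with that trend removed 2 rose and 1 fell. Of 10 S100 genes, for calcium-binding proteins, 7 fell and 1 rose, with S100A2 going from 241 ± 24 to 104 ± 2.9 TPM; S100A13, the gene that rose, did not pass the threshold under median-of-ratios scaling. Serpins fell in 7 of 9 cases with none rising, with SERPINB2 going from 14.2 ± 1.9 to 7.16 ± 0.05 TPM, and IGF binding proteins in 4 of 6 with none rising, with IGFBP6 going from 35.2 ± 4.6 to 16.6 ± 1.5 TPM.

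Keratins went both ways, with 6 of 11 falling and 2 rising: KRT17 fell from 39.3 ± 3.0 to 10.3 ± 1.8 TPM and KRT16 from 4.67 ± 0.80 to 1.65 ± 0.42 TPM, while KRT8 and KRT18, the simple epithelial pair, which overlap in the annotation, rose. KRT18 went from 3149 ± 57 to 3859 ± 13 TPM. RNA polymerase subunits rose in 16 of 33 cases with none falling, with POLR2J3, which did not pass the threshold, counted under separate gene IDs. For comparison with these families, 2773 of all 11906 kept protein-coding genes rose and 1741 fell. Of 17 heat shock protein genes 5 rose and 3 fell, and under median-of-ratios scaling 5 rose and 5 fell. Of 4 metallothioneins 2 rose and none fell, and under quantile normalisation 1 rose; MT2A went from 10618 ± 783 to 15901 ± 265 TPM. FRG2B and the DUX4-like pseudogenes, repeated sequences found near chromosome ends among other places, fell in 4 of 6 cases with none rising, which counts copies that share reads. Genes typed as other than protein-coding fell more often than they rose, 290 against 146 of 2433, and made up 93 of the 311 genes at least 2-fold lower. A further 110 of the 311 are not in the annotation used, and their type is not known. Under median-of-ratios scaling 14 RNA polymerase subunits rose instead of 16, and under quantile normalisation 15. The counts of falling serpins, IGF binding proteins and keratins were the same under both.

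The 6 samples can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real groups gave 5135 genes past the threshold and 378 at least 2-fold, and the highest of the other splits 2 and 2; 1 split of 10, the real one, reached each value. The real groups gave 14 called lists and another split 12, with 1 of 10 splits reaching 14, so camera with the preset correlation also called many lists between mixed groups. Every other split mixes the 2 groups unequally, so part of the group difference stays in it and part adds to the spread. The splits therefore do not show what groups without a difference would give, for genes or for lists.

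Of 36 interferon-stimulated genes 21 fell, as did 3 interferon lambda genes. The trend that was removed, over the median GC content and length of each gene's annotated transcripts, does not account for this. The list's median log2 fold change was -0.54 before and -0.59 after the removal, with 24 of 36 members then falling and 1 rising. Which transcripts were measured is not known, so a trend over their own GC content and length is not excluded. Whether lower interferon lambda transcripts, at a log2 fold change of -1.82 for IFNL1, came before or after these changes was not tested, and no value here decides it. A difference between the vectors or the transduced populations apart from CTSZ cannot be told apart from the knockdown, because the series has 2 groups and neither is untransduced or rescued.

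Of 34 histones 14 fell and none rose, while 26 of 37 S phase genes rose and none fell. Fewer cells in S phase might lower the S phase list, whose median log2 fold change was 0.39. The transcripts of that list do not count cells in S phase, so its rise cannot decide this. The GC and length trend that was removed, over annotated transcripts, does not account for all of the histone change, since the histones' median went from -0.52 to -0.42. The list stayed called at the preset correlation (camera adjusted p = 2.34e-04). With an estimated correlation it was not called, either with the trend removed (camera adjusted p = 0.137) or before (0.136, the highest of its alternatives). Messengers of replication-dependent histones mostly lack a poly(A) tail, so a lower yield of such RNA may contribute. Which forms of these messengers were measured is not known. Other RNAs that lack this tail had a median log2 fold change of 0.0557 over 22 genes, with a bootstrap 95% interval from -0.27 to 0.67 that is too wide to decide.

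The fall of log2 fold change with GC content was also present outside the gene lists, with a rho of -0.35 over 11150 of the 11896 protein-coding genes. The lists hold few of these genes, so leaving them out could hardly have changed rho. A library preparation that recovered GC-rich RNA less well in the shCTSZ libraries could give such a trend and would act on other RNA too. Across 2428 genes that are not protein-coding rho was -0.0359, against -0.37 in 2354 protein-coding genes drawn to match their mean TPM. The draw was made once and did not match length. Since TPM keep no read totals, these sets may differ in the precision of their fold changes, which was not tested. With the trend over GC content and length removed, rho in the genes that are not protein-coding was 0.11. The rho of -0.0359 is weaker than such a preparation predicts but is not 0 or above. The GC content of these genes may rest on less certain transcript models, which was not tested. A change of GC-poor against GC-rich messengers in the cells stays open, as untested, because the trend follows the groups.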
